A study of Homo sapiens with 9 samples.

How the data were processed

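Genomic DNA was taken from HCT116 WT cells, HCT116 DKO cells and postmortem human brain of the subventricular zone. Per the labels' protocols, 1 µg of DNA was sheared to a mean of 300 bp, ligated to adapters, precipitated with a 5mC or 5hmC kit or with nonspecific IgG, size-selected at 200 to 400 bp and amplified for 18 PCR cycles. Of the 9 samples, 6 had a peak list used here, and the IgG libraries of the other 3 were not analysed here, so no background from the controls is given. Each group had 1 library. Groups were taken from the sample titles.

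Peaks were called with MACS on the hg19 build, per the submitters' processing notes. The version, thresholds, control library, read filters and duplicate handling are not given in the sources used here. Each list belongs to 1 sample, and nothing in the labels says that samples were pooled. Each deposited HCT116 list carries 1 value per peak, taken here as a fold enrichment (a linear ratio over the background of the caller). Each deposited brain list carries a score taken here as −log10 of a p-value or q-value. Neither kind is named by the labels, and both were inferred from the values. A check of their spacing is given here for the PGM lists alone. On the PGM, 32.4% of the WT values and 14.9% of the DKO values were whole multiples of 1 unit within rounding, so the inference is less firm in DKO. The unit was derived from the commonest value, so the peaks at that value, 12.6% in WT and 4.95% in DKO, counted by construction. The values are the authors' own and were used to rank or describe peaks within a list, except for 1 setting that applied the median of the WT Proton list as a threshold to all HCT116 lists. MACS settings could change the number of peaks, their width and their overlap, and a deeper library gives more peaks at the same threshold. Depth per sample is unknown.

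The largest position on chromosome 1 lies beyond the last gene end on that chromosome in the GRCh38 gene table. That table was the only gene annotation at hand and was not used for coordinates. Promoters, gene lists and the distribution of peaks over genes had been planned and were not run, since no hg19 annotation was used here. Starts were read as counted from 0 and are printed as counted from 1, and a list exported with another convention would be shifted by 1 base. Autosomes were used throughout, and peaks on other sequences were left out of the comparisons.

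Peaks of different lists were called shared when they overlapped by at least 1 bp. A script in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 counted them, and bedtools 2.31.1 gave the same counts for 3 pairs, such as 43622 WT Proton peaks in the DKO Proton list. Figures were drawn with matplotlib 3.10.9. Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only, and the SD over 22 autosomes. Chance overlap is the mean of 100 circular shifts of the other list within each chromosome (seed 11). The overlap count was tested on simulated data: of 163928 simulated peaks modelled on WT against DKO on the Proton, 39.9% had been planted as shared and 39.9% were recovered, with 0 wrong. Unrelated simulated lists overlapped at 1.18%, against 1.15% from the shifts. Those lists were placed at random along each chromosome, so this does not test the shifts on real peaks, which are unevenly spread. For WT in DKO on the Proton, shifts of 50 to 500 kb gave 1.73%, against 1.20% from the circular shifts.

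The list comparisons, their overlap measures, the rule for named peaks and the settings listed next were fixed before the data were examined. The rule for named peaks, used in the absence of an hg19 annotation, takes the 5 highest-scoring peaks of each class, of which the text gives the leading ones. The other settings fixed then were 50% coverage of the queried peak, the 50% of each list with the highest scores, equal numbers of the highest-scoring peaks, merging within 500 bp, the PGM in place of the Proton, all chromosomes for HCT116, uniform placement for chance, and the median WT Proton score as a threshold for peak numbers. Uniform placement was coded in Python and not with bedtools as planned. Chosen after the data were examined were the 1 Mb windows with their minimums of 40 and 10 peaks and limit of 10%, the windows with at least 20 WT and DKO Proton peaks together, peak-free stretches of over 1 Mb in all 6 lists with a margin of 2 Mb, the 100 highest-scoring brain peaks, sites kept or lost by fold enrichment, the correlations (3 across autosomes, 2 across windows), windows grouped by WT over brain 5mC peaks, shifts of 50 to 500 kb, and the removal of brain peaks found in HCT116. There were 24 peak-free stretches with 181.0 Mb in all.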

Results

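Methylated DNA immunoprecipitation followed by semiconductor sequencing (MeDIP-seq on Ion Torrent instruments) was used to map 5-methylcytosine (5mC) in HCT116 cells, and 5mC and 5-hydroxymethylcytosine (5hmC) in human brain. In this assay an antibody pulls down sheared DNA that carries the modified base, and a peak is a place where the recovered reads pile up above background. HCT116 is a colon cancer cell line. WT denotes the parental line and DKO a derivative in which the DNA methyltransferase genes DNMT1 and DNMT3B are disrupted. The brain sample was postmortem tissue of the subventricular zone, a layer along the lateral ventricles. The series held 9 samples, 1 library per group. Peak lists of 6 samples were analysed: HCT116 WT and DKO on each of 2 instruments, the Proton and the PGM, and brain 5mC and brain 5hmC. The IgG control libraries of the other 3 samples were not analysed here. Sequencing depth is unknown, since the lists hold no read counts.

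On the autosomes, the WT list held 163927 peaks on the Proton and 37043 on the PGM, and the DKO list held 82680 and 22392. The brain 5mC list held 215075 peaks and the brain 5hmC list 144367. After merging, the peaks covered 34.5 Mb in WT and 16.4 Mb in DKO on the Proton, 9.19 Mb and 5.80 Mb on the PGM, 44.6 Mb for brain 5mC and 19.2 Mb for brain 5hmC. Median peak width was 191 bp and 181 bp on the Proton for WT and DKO, 217 bp and 235 bp on the PGM, 184 bp for brain 5mC and 116 bp for brain 5hmC. Each list had its own smallest width. It was 150 bp and 151 bp on the Proton, 201 bp and 212 bp on the PGM, 138 bp for brain 5mC and 95 bp for brain 5hmC. On the PGM the lower quartile equalled that minimum. Differences in width between lists are therefore not read as differences between methylated sites. With 1 library per group, no difference below has a replicate check and no p-value is given. The SD over the 22 autosomes shows how evenly a value was spread along the genome, and the 95% exact intervals cover counting error only.

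The first comparison asked how the map of 5mC changes when both methyltransferase genes are disrupted. DKO cells had fewer peaks than WT cells on both instruments, with a ratio of 0.504 on the Proton and 0.604 on the PGM. The ratio of covered length was 0.475 on the Proton and 0.631 on the PGM. Each library started from 1 µg of DNA, and each list belongs to 1 library. A number of peaks is therefore not an amount of methylation. A peak called in DKO and not in WT does not by itself show a gain. Of the WT peaks, 26.6% were also called in DKO on the Proton (95% interval 26.4 to 26.8, SD over autosomes 3.48), against 1.20% after circular shifts of the DKO list. On the PGM the share was 14.4% (14.1 to 14.8, SD 2.52), against 0.405% by chance. In the other direction, 52.8% of the DKO Proton peaks overlapped a WT Proton peak (52.4 to 53.1, SD 3.21, chance 2.39%), so that 39035 DKO peaks had no WT counterpart in that list. The share of WT peaks called in DKO fell to 14.2% when only the 50% of each list with the highest scores was kept, and rose to 32.9% with equal numbers of the highest-scoring peaks. The share of DKO peaks called in WT fell to 28.2% and 33.0% under these settings. With equal numbers only the longer WT list was cut, to its highest-scoring peaks. That left fewer WT peaks for a DKO peak to overlap, so the share of DKO peaks called in WT could only fall.

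**Figure D1:**
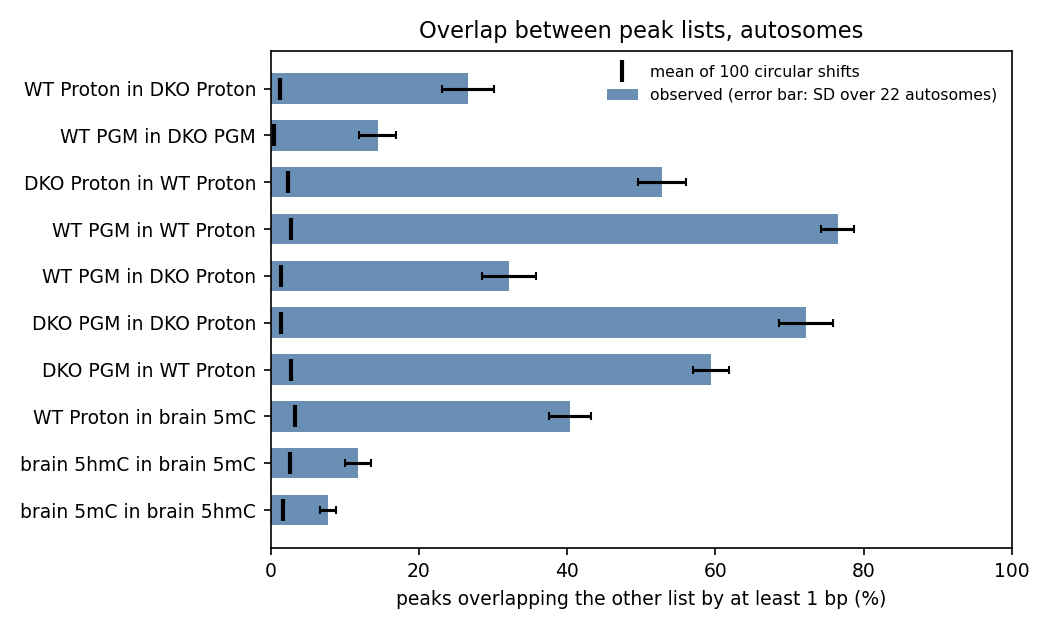
Share of the peaks of the first list that overlap the second list by at least 1 bp, in percent, for 10 ordered pairs of lists. Bars show the observed share, error bars the SD over 22 autosomes, and vertical ticks the mean of 100 circular shifts, which lies at 3.22% or lower for every pair shown.

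Peaks called on both instruments gave a stricter view. Of 28564 WT Proton peaks that also had a WT PGM peak, 16590 (58.1%, 57.5 to 58.7, SD over autosomes 4.76) overlapped no DKO peak on either instrument. DKO peaks were present on both instruments at 4081 of them (14.3%, 13.9 to 14.7, SD 3.0), on the Proton alone at 7229 and on the PGM alone at 664. Of 16273 DKO Proton peaks also called in DKO on the PGM, 4781 (29.4%, 28.7 to 30.1, SD 2.77) overlapped no WT peak on either instrument. WT peaks with higher fold enrichment were called in DKO more often: 42.4% (SD over autosomes 4.88) of the quintile with the highest values against 22.5% (SD 3.66) of the quintile with the lowest, although the lowest share, 18.3%, was in the next quintile up. DKO Proton peaks went the other way: 70.6% of the quintile with the lowest values were called in WT, 55.5, 43.5 and 40.8% of the next ones, and 53.5% of the highest. The median fold enrichment of WT Proton peaks was 14.5 at sites called in all 4 HCT116 lists and 11.5 at sites called in WT alone.

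The peaks with the highest values in each class are given by their hg19 coordinates, without gene names, because no hg19 annotation was used here. Among sites called in WT on both instruments and in DKO on neither, the highest WT Proton fold enrichment was 70.0 on chromosome 10 at 115661526 to 115661851, where the WT PGM value was 19.5. The next were 66.7 on chromosome 10 at 3678684 to 3678979 and 61.0 on chromosome 20 at 4863153 to 4863430. Among sites called in DKO on both instruments and in WT on neither, the highest DKO Proton value was 70.8 on chromosome 3 at 193021338 to 193021588, with 9.85 on the PGM. It was followed by 57.9 on chromosome 11 at 121761810 to 121762128 and 54.9 on chromosome 9 at 84002737 to 84003048. Among sites called in all 4 lists, the WT Proton value reached 60.1 on chromosome 17 at 78855819 to 78856181, where the DKO Proton value was 8.60. Chromosome 11 at 61051777 to 61052099 had 59.0 in WT and 9.17 in DKO. Fold values belong to their own list and do not measure a change between lists.

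Chromosomes differed in how far the number of peaks was lower in DKO. Chromosome 19 had the lowest DKO to WT ratio on both instruments, 0.301 on the Proton and 0.323 on the PGM. Chromosome 16 had 0.351 and 0.432, and chromosome 20 had 0.380 and 0.434. Chromosome 13 had the highest autosomal ratio, 0.672 on the Proton and 0.837 on the PGM. Across the 22 autosomes the mean ratio was 0.498 ± 0.0840 (SD over autosomes) on the Proton and 0.597 ± 0.108 on the PGM. The ratios of the 2 instruments correlated across autosomes with Pearson's r of 0.968 and Spearman's rho of 0.934, and r was 0.945 without chromosomes 16 and 19. Autosomes of the same libraries are not independent samples, so no p is given.

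**Figure D2:**
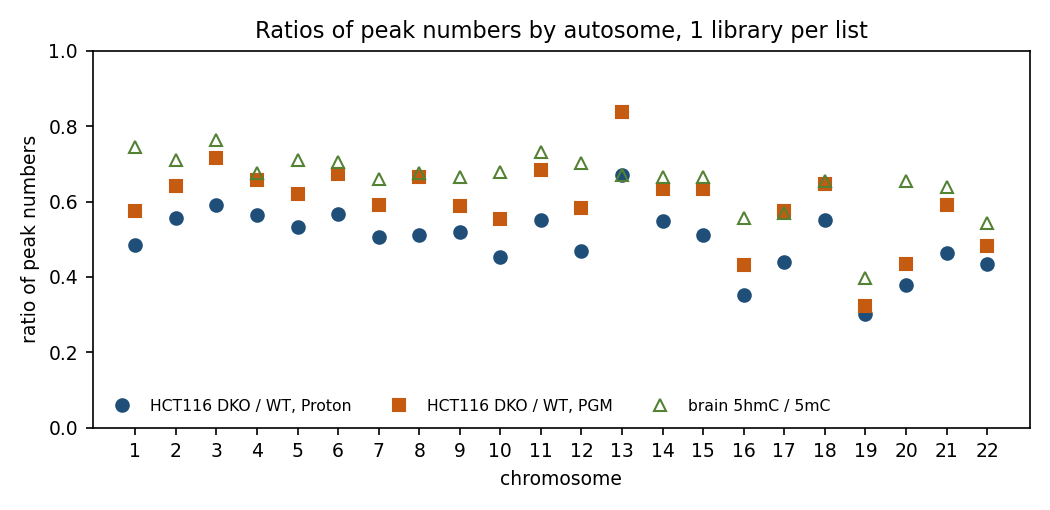
Ratio of peak numbers (vertical axis, no unit) on each of the 22 autosomes (horizontal axis) for HCT116 DKO over WT on the Proton (circles) and the PGM (squares), and for brain 5hmC over 5mC (triangles), from 1 library per list. Chromosome 19 is lowest in all 3 series, at 0.301, 0.323 and 0.398.

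At a scale of 1 Mb, most windows had fewer peaks in DKO, and a smaller set had more. Of 2471 windows with at least 20 Proton peaks in WT and DKO together, DKO had fewer in 2302 (93.2%) and more in 150 on the Proton. On the PGM it had fewer in 1852 (74.9%) and more in 484, and 114 windows had more on both instruments. The highest DKO to WT ratios away from long peak-free stretches were in windows with few WT peaks, where a ratio rises most easily. Chromosome 4 from 21 to 22 Mb had 34 DKO and 4 WT peaks on the Proton, and 12 and 0 on the PGM. Chromosome 4 from 23 to 24 Mb had 40 and 5 on the Proton and 13 and 2 on the PGM. Chromosome 16 from 76 to 77 Mb had 31 and 5, and 9 and 0. Chromosome 18 from 53 to 54 Mb had 41 and 8, and 13 and 3.

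Windows rich in WT peaks were examined for near absence of DKO peaks. Among 1456 windows with at least 40 WT Proton and 10 WT PGM peaks, a filter that favours low ratios, the median DKO to WT ratio was 0.482 on the Proton and 0.538 on the PGM. In 31 of them DKO had at most 10% as many Proton peaks as WT. Of these, 5 lay away from long peak-free stretches and had no DKO peak on either instrument: chromosome 5 from 2 to 3 Mb, chromosome 10 from 130 to 131 Mb and from 131 to 132 Mb, and chromosome 12 from 115 to 116 Mb and from 130 to 131 Mb. They held 43 to 57 WT Proton peaks and 10 to 21 WT PGM peaks. Among the windows rich in WT peaks, the highest ratio was on chromosome 11 from 129 to 130 Mb, with 155 DKO and 91 WT peaks on the Proton and 63 and 15 on the PGM. All windows and limits were chosen after the data were examined. The number of low windows was 58 with a minimum of 20 WT Proton peaks alone and 8 with a minimum of 80.

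**Figure D3:**
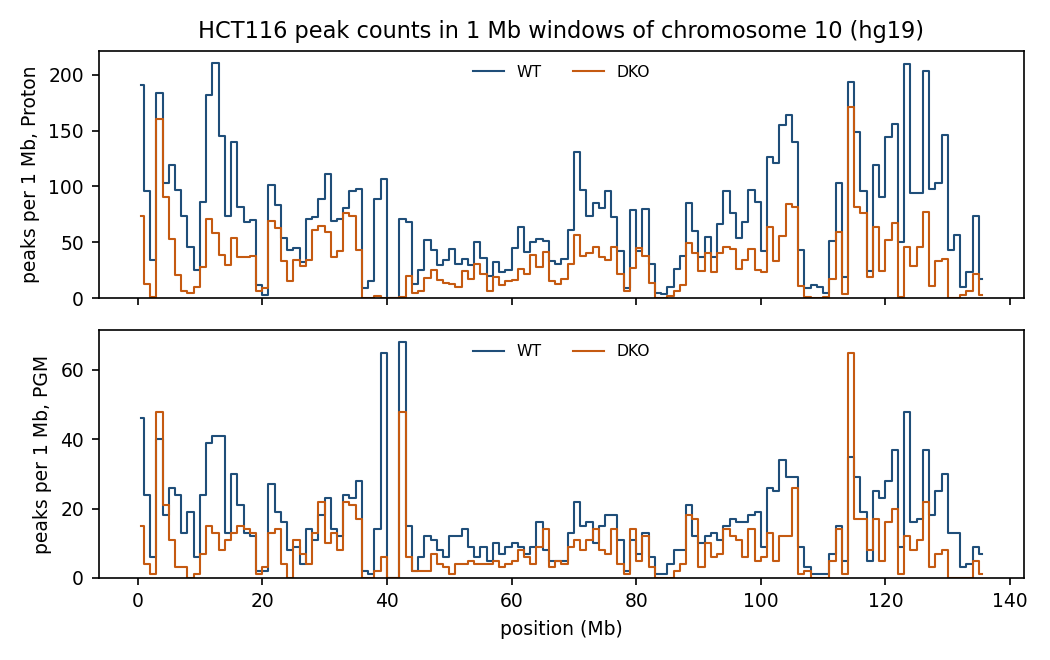
Number of HCT116 peaks in each 1 Mb window (vertical axes) along chromosome 10 in hg19 (horizontal axis, Mb), for WT and DKO on the Proton (top) and the PGM (bottom), 1 library each. In the windows from 130 to 132 Mb, WT had 43 and 57 Proton peaks and 13 PGM peaks in each, and DKO had none on either instrument.

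HCT116 WT and DKO each had a list from both instruments, which allowed the call of a peak to be compared between them. The Proton list was longer than the PGM list 4.43 times in WT and 3.69 times in DKO. Of the WT PGM peaks, 76.5% (76.1 to 76.9, SD over autosomes 2.23) were also called in WT on the Proton, and 32.1% (31.7 to 32.6, SD 3.61) in DKO on the Proton. Of the DKO PGM peaks, 72.2% (71.7 to 72.8, SD 3.60) were also called in DKO on the Proton, and 59.4% (58.8 to 60.1, SD 2.46) in WT on the Proton. The list of the same genotype held the larger share on 22 of 22 autosomes in both cases. WT PGM peaks of the quintile with the highest fold enrichment were found in the WT Proton list at 94.6%, against 60.0% of the quintile with the lowest. When the whole PGM list was set against only as many of the highest-scoring Proton peaks, the share was 39.1% in WT and 29.2% in DKO. The labels do not say whether the instruments shared a library.

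In brain, a small share of the peaks of each antibody overlapped the other, though more than by chance. Of the 5hmC peaks, 11.8% (11.6 to 11.9, SD over autosomes 1.70) overlapped a 5mC peak, which was 4.56 times the 2.58% found after circular shifts. Of the 5mC peaks, 7.74% (7.63 to 7.85, SD 1.03) overlapped a 5hmC peak, 4.52 times the chance value of 1.71%. For scale, between the instruments with 1 antibody and genotype, 76.5% of the shorter WT PGM list overlapped the longer WT Proton list, and 17.4% of the longer list overlapped the shorter. The 5hmC list had 0.671 times as many peaks as the 5mC list and covered 0.430 times the length, with a smallest peak width of 95 bp against 138 bp. The ratio of 5hmC to 5mC peaks was lowest on chromosome 19, at 0.398, and highest on chromosome 3, at 0.764, around a mean of 0.656 ± 0.0800 (SD over 22 autosomes). Among 1 Mb windows with at least 40 5mC peaks away from long peak-free stretches, the ratio was highest on chromosome 5 from 11 to 12 Mb, with 108 5hmC and 45 5mC peaks. It was lowest on chromosome 9 from 40 to 41 Mb, with 5 and 71, and next lowest from 39 to 40 Mb, with 4 and 50.

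Overlap between the brain lists rose with the score. Of the 5hmC peaks, 24.8% (24.3 to 25.3) of the quintile with the highest scores overlapped 5mC, against 6.92% (6.63 to 7.22) of the quintile with the lowest. For 5mC peaks the shares were 12.6% and 5.70%. Brain peaks shared by both antibodies were also called in HCT116 more often: 49.8% of the shared 5hmC peaks overlapped the WT Proton list, against 10.5% of the 5hmC peaks without a 5mC peak. For 5mC peaks with and without 5hmC the shares were 50.7% and 29.0%. The HCT116 lists are themselves 5mC lists, so 5hmC peaks chosen for lying on a brain 5mC peak were favoured. Shared peaks were also wider, with medians of 132 bp against 115 bp for 5hmC and 196 bp against 183 bp for 5mC. Their median scores were higher too, 8.275 against 6.12 and 11.5 against 9.26. Neither width nor score was held equal. Without the brain peaks that overlap an HCT116 list, the share of 5hmC peaks overlapping 5mC was 6.21%, and that of 5mC peaks overlapping 5hmC 5.12%, settings added after the data were examined. Requiring 50% of the 5mC peak to be covered gave 4.85%.

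The highest-scoring brain peaks are again given by position. Among sites called by both antibodies, the 5mC score, taken as −log10 of a p or q value, was highest on chromosome 11 at 85194965 to 85195287, with 622.5 for 5mC and 352.4 for 5hmC. The next were chromosome 1 at 145277252 to 145277571, with 616.9 and 34.3, and chromosome 8 at 70602250 to 70602715, with 588.3 and 147.2. Of the 100 highest-scoring 5mC and 5hmC peaks, 28% and 24% lay within 2 Mb of a long peak-free stretch, against 3.32% and 3.65% of all. Repeats collapsed in the assembly may account for part of such scores. The sites just named lay outside that margin, but repeats elsewhere were not tested and no IgG list was used. The highest 5mC peak without 5hmC lay on chromosome 8 at 56754998 to 56755363, with a score of 404.6. The highest 5hmC peak without 5mC scored 217.0 on chromosome 1 at 9955 to 10486, near the start of that chromosome. It was followed by 213.0 on chromosome 9 at 6594674 to 6594838, a site also called in HCT116 WT on both instruments and in DKO on the PGM. Chromosome 16 at 33888483 to 33888729 had 186.5 and chromosome 2 at 91615854 to 91616016 had 181.85, both within 2 Mb of a long peak-free stretch. Chromosome 18 at 9980 to 10359, again near the start, had 180.9. Whether repeats gave these peaks was not tested.

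As a side comparison of the cell line with the tissue, 40.4% of the WT Proton peaks overlapped a brain 5mC peak (40.1 to 40.6, SD over autosomes 2.85), 12.5 times the chance value of 3.22%. The share differed with what happened in DKO. It was 62.4% (60.9 to 63.9, SD 6.44) at sites called in all 4 HCT116 lists and 48.6% (47.9 to 49.4, SD 3.33) at sites called in WT on both instruments and in DKO on neither. It was 26.2% (24.9 to 27.4, SD 4.27) at sites called in DKO on both instruments and in WT on neither. Sites kept in DKO exceeded lost sites on 22 of 22 autosomes, and within every quintile of WT fold enrichment by 5.60 to 12.2 percentage points. Median peak width ran in the same order as the share: 264 bp in all 4 lists, 229 bp in WT alone and 200 bp in DKO alone. Width was not held equal, and a wider peak overlaps another more easily. The cell line and the tissue differ in source and in the score their lists carry, and nothing in the design separates these.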

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

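The results in this part lie outside the comparisons of the report, and no technical or biological explanation was tested for them. Peaks on the mitochondrial sequence were found in the brain 5mC list, with 15 peaks covering 6727 bp. That number is above the limit of 3 that a count of 0 allows, a limit for random counts and not for called peaks. The brain 5hmC list had 3 such peaks covering 6641 bp, nearly the same length, and the 4 HCT116 lists had 0. Whether mitochondrial reads were kept for the HCT116 lists is not known. No control library was analysed here to set this against.

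Chromosome X of the HCT116 cell line was left out of the comparisons. It held 2240 WT and 1716 DKO peaks on the Proton, a ratio of 0.766, and 512 WT and 438 DKO peaks on the PGM, a ratio of 0.855. Both ratios were above that of every autosome on the same instrument, of which the highest was 0.672 on the Proton and 0.837 on the PGM. The PGM ratios lay close together, and no interval was computed for them. Of the WT peaks on chromosome X, 31.1% (29.2 to 33.1) were also called in DKO on the Proton and 17.4% (14.2 to 20.9) on the PGM. These shares were below those of chromosome 13, 34.0% on the Proton and 20.2% on the PGM.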

How the results depend on the processing

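With 1 library per group, a share counted as moved when it left its 95% binomial interval, which is narrow with lists this long: 33 of 39 alternatives did and 6 did not. Main values follow in the order WT in DKO on Proton, WT in DKO on PGM, DKO in WT on Proton, WT PGM on Proton, DKO PGM on Proton, 5hmC in 5mC, 5mC in 5hmC, and WT in brain 5mC. They were 26.6, 14.4, 52.8, 76.5, 72.2, 11.8, 7.74 and 40.4%. With 50% of the peak covered they were 25.1, 13.4, 51.2, 73.3, 68.6, 10.2, 4.85 and 37.2%. In the 50% of each list with the highest scores they were 14.2, 9.65, 28.2, 72.1, 57.2, 10.7, 6.99 and 33.5%. With equal numbers of peaks they were 32.9, 18.0, 33.0, 39.1, 29.2, 8.91, 8.69 and 34.6%. With equal numbers only the longer list of a pair was cut. For DKO in WT, PGM on Proton, 5hmC in 5mC and WT in brain 5mC that was the other list, so the share could only fall. In the remaining pairs the queried list was cut to its highest-scoring peaks. Keeping the highest-scoring 50% shortened both lists. Other causes were not tested. Merging within 500 bp moved WT in DKO on Proton to 27.9%, DKO in WT to 53.5%, 5mC in 5hmC to 7.99% and WT in brain 5mC to 41.9%. The PGM in place of the Proton gave 14.4% for WT in DKO. Among settings added after seeing the data, leaving out peaks near peak-free stretches gave 14.0% for WT in DKO on PGM and 10.8% for 5hmC in 5mC, and leaving out brain peaks found in HCT116 gave 6.21% for 5hmC in 5mC and 5.12% for 5mC in 5hmC. The cause of these moves was not tested either. The DKO to WT ratio of peak numbers stayed below 1 and within 1.5 times its main value in all 6 alternatives, from 0.504 to 0.641 on the Proton and from 0.604 to 0.820 on the PGM, highest at the score threshold. Chance from shifts of 50 to 500 kb, also added, lowered WT in DKO from 22.1 to 15.4 times chance and 5hmC in 5mC from 4.56 to 3.73 times. Promoters, gene lists and genomic distribution with their alternatives were not run. Unknown depth limits every ratio of peak numbers. No paired analysis was possible because each group has 1 library and the results come from no test.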

Other observations

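All tests in this part were chosen after the results they bear on had been seen, and the reading of the top brain peaks over all 4 HCT116 lists replaced one from the WT PGM list alone, which the data had met. No biological explanation was tested for those peaks. The ratios of peak numbers in HCT116 and in brain varied together across autosomes: DKO over WT on the Proton correlated with brain 5hmC over 5mC at Pearson's r of 0.724 and Spearman's rho of 0.649 over 22 autosomes. Without chromosomes 16 and 19, r was 0.466, so much of the relation rests on those chromosomes. With the PGM ratio r was 0.725 and rho 0.570, and r was 0.671 without chromosomes 13 and 19. Across 1456 windows of 1 Mb the Proton ratio and the brain ratio had a Spearman's rho of 0.380, and the Proton and PGM ratios 0.736. Neither autosomes nor windows are replicates, and no p is given.

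A negative result concerns windows with few WT peaks for their number of brain 5mC peaks. When windows were grouped into quintiles by WT PGM over brain 5mC peaks, the pooled DKO to WT ratio on the Proton was 0.491, 0.506, 0.490, 0.507 and 0.492 from the lowest to the highest, with no trend. With the instruments exchanged, the pooled PGM ratio was 0.607, 0.546, 0.586, 0.611 and 0.617. The median window told another story for the lowest quintile alone, with 0.368 on the Proton and 0.333 on the PGM, against 0.50 or more on the Proton and 0.571 or more on the PGM in the others.

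The DKO lists were shorter than the WT lists, and a shallower DKO library would also shorten a list. A short list alone would hold WT PGM peaks about as often as DKO PGM peaks, if both PGM lists were equally strict. The DKO Proton list held DKO PGM peaks more often by 40.1 percentage points (SD over autosomes 2.46, higher on 22 of 22). The WT PGM list is longer, and it held 21.6% of that list's quintile with the lowest values, against 47.5% of the highest. The longer WT PGM list could thus give part of the difference. Even 47.5% is below the 72.2% of all DKO PGM peaks, which argues against list length as the whole cause. The difference does not show how much of the lower peak number comes from depth. If each line was read on both instruments from a single library, features of that library could give the same excess, and the labels do not settle this. A loss of methylation in DKO stays open as a hypothesis.

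In 31 windows of 1 Mb, DKO had at most 10% as many Proton peaks as WT. In the 23 of them away from peak-free stretches the pooled PGM ratio was 0.0382, below the lowest of 1000 random sets of 23 such windows (0.376), which argues against scatter of calls on the Proton alone. Of the 31, 8 lay near peak-free stretches, where repeats are a candidate source, and those had a PGM ratio of 0.393. Of all WT Proton peaks 2.28% lay near such stretches, but a share of peaks is no base for a number of windows. How many of all 1456 windows lay there is not given, so an excess of low windows there is not shown. Repeats away from those stretches were not tested. More than 3 DKO peaks over both instruments argue against deletion of the whole window in the DKO line for 13 of the 23, while in the 10 with 0 to 3 DKO peaks deletion and loss of methylation cannot be told apart, since the lists hold no input coverage. Blocks of lost methylation are a hypothesis for the 13 windows, with a shared library, repeats and smaller deletions untested.

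Of the 100 highest-scoring brain 5mC peaks 87% overlapped 5hmC, and of the top 5hmC peaks 98% overlapped 5mC, against 7.74% and 11.8% of all. Near peak-free stretches lay 28% and 24% of them, against 3.32% and 3.65% of all, so repeats collapsed in the assembly may account for part of them, and repeats elsewhere were not tested. A signal independent of the cell source would be present in HCT116 too: 41% and 47% of the top peaks overlapped the WT PGM list, against 7.77% and 5.32% of all, and 21% and 28% the DKO PGM list, against 3.98% and 3.49%. In the WT Proton list it was 31% and 33%, against 30.6% and 15.2%, and in the DKO Proton list 4% and 2%, against 14.7% and 8.15%, so both PGM lists differ from the DKO Proton list and the question stays open.

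The fold values on the PGM were checked for whole pileups over 1 background, for which at least 20% of the values were required to be whole multiples of 1 unit. WT reached 32.4% and DKO only 14.9%, so the requirement was missed in DKO and the kind of value stays undecided there. The unit was the commonest value of each list divided by a whole number. Peaks at that value, 12.6% of WT and 4.95% of DKO, therefore counted by construction. They are part of the 32.4%, so the check is weaker in WT than that share implies.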
